A study of Mus musculus with 12 samples.

How the data were processed

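RNA of bone marrow from C57BL/6 mice was sequenced in 12 samples, 3 in each of 4 groups: young controls (Young-CON), young mice with traumatic brain injury (Young-TBI), aged controls (Aged-CON) and aged mice with traumatic brain injury (Aged-TBI). Marrow of the injured groups was collected 3 days after injury, per the labels. Total RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA-seq kit, per the labels' protocols. The submitters' processing notes name GRCm38, mm10 and R 4.3.3. The aligner, the counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Samples are named by group and number, such as Aged-CON 1. The labels do not say whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

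The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) per gene symbol and sample, with 24421 entries and all 12 samples. FPKM corrects for gene length and depth, and it is a relative measure: a rise of abundant genes in a sample lowers the values of the others. Of the entries, 27 carried names that a spreadsheet had turned into dates; 19 of them were tested but not named. A symbol in the GENCODE M21 or RefSeq tables was found for 23615 entries and for 11378 of the tested genes. Coordinates are those of GENCODE M21 on GRCm38. The symbols of the table do not separate near-identical members of multigene families, so values of H2-Q4, H2-Q5, Apol11a, Apol11b, Stfa2, Wfdc17, Hist1h4k, Hist1h1c, Vmn2r96 and Dynlt1b are uncertain. Of 81 genes named by the rule below, 12 overlap another tested gene, 8 of them on the opposite strand (Cebpb, Csf1r, Il1b, Junb, Psmb9, Vpreb1, Cd72 and Chchd10) and the rest on the same strand (Cd74, Hint3, Fam129c and Rag1). Fragments of such partners may have been counted together.

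Low FPKM values fell on steps that are whole multiples of the value of 1 fragment. For 99.8% of the tested genes (11748) the steps gave whole fragments within a tolerance of 0.05. The recovered totals ran from 12.3 to 15.9 M fragments per sample, and the relative depth of the deepest against the shallowest sample was 1.29. The sums of FPKM lay between 470060 and 500880, and between 11147 and 11481 genes reached 1 FPKM in a sample. S100a8 and S100a9, the most abundant transcripts of neutrophils, made up 7.87% to 12.3% of the sum, and the 10 highest genes 14.8% to 21.4%. Each of the 12 pairs of samples within a group differed by more than counting noise (chi-square over degrees of freedom 4.48 to 49.4 over 11178 genes), so every sample was counted as its own library. As an average over these genes, counting noise was smaller than the spread between samples. This average does not show the same for genes with few fragments.

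Genes with at least 1 FPKM in at least 3 of the 12 samples were kept, which left 11767 genes. Values were taken as log2(FPKM + 1), with no further scaling between samples, and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 samples in the same fit and a variance trend on expression. A log2 change is on that scale and understates the change of genes near 1 FPKM. Tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over all tested genes. Genes are said to have risen or fallen at an adjusted p under 0.05. Each adjusted p of a gene is from limma. The 5 comparisons were injury in young mice, injury in aged mice, age without injury, age after injury, and the interaction of age and injury, which is the aged injury effect minus the young. Their 4 pairwise members share libraries: the Aged-CON samples enter both the aged injury comparison and the age comparison of controls, with opposite signs, and the Young-CON samples likewise.

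Lists of genes were fixed for marrow cell types, other tissue that marrow can hold, signalling and stress responses, and large complexes. Of 39 lists, 38 had tested members; 12 listed symbols had no entry and 3 were found under an older name. Each list was compared with all other genes by camera, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. It was repeated with the correlation estimated from the data, and fry tested whether a list's members moved on balance one way. Members were also adjusted over the list alone. The genes named are, for each comparison, the 8 largest rises and 8 largest falls whose groups did not overlap and whose higher group mean was at least 5 FPKM (for the interaction, without the condition on overlap). To these were added up to 4 called members per list with the smallest adjusted p, the 3 genes with the smallest p where a direction had fewer than 3, and 14 fixed genes. Of those fixed genes, Adrb1, Adrb3 and the haemoglobin gene Hbb-bs stayed under the level filter and were not tested. Some called list members were left out of the text to stay near 30 genes per comparison, and some genes that the rule selects are not reported here.

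The comparisons, tests, lists, rule for named genes and most alternatives were set before the data were examined. These alternatives were a pseudocount of 0.1, no low-value filter or a mean of at least 5 FPKM, and 3 other scalings. Further ones were the replicate number as a block, weights per sample, no variance trend, a minimum log2 change of 1, a fit of only the samples compared, and each sample left out in turn. After the data were seen, 3 more were added: limma voom on the recovered fragments, the mean of the erythroid list as a covariate, and a fit without Young-CON 2 and Aged-CON 1, which stood apart from the other 2 controls of their age. The controls left in that fit had erythroid list means of 7.30 and 7.12 in Young-CON and 6.66 and 6.58 in Aged-CON. It therefore joins the age of the controls with their erythroid level. The procedure was tested on simulated data with the real group sizes, in which 198 of 11597 genes were changed. In a simulated aged injury comparison it recovered 91.9% of changes of 1 on the log2 scale and 52.5% of changes of 0.58, and 5.92% of its calls were false. In a simulated age comparison after injury these shares were 91.9%, 55.6% and 7.01%, and in a simulated interaction 77.8%, 26.3% and 5.50%. The simulated noise was independent between genes, and no sample was set apart. The real samples differed in factors shared by many genes, so these shares do not carry over to the real comparisons. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. Immunoglobulin and T cell receptor variable segments and predicted genes were tested but not named.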

Results

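Bone marrow is where blood cells are made, and the series asks how traumatic brain injury (TBI) and age change myelopoiesis there and what part adrenergic signalling plays. RNA was measured as FPKM in 12 samples, 3 each of Young-CON, Young-TBI, Aged-CON and Aged-TBI, at 12.3 to 15.9 M recovered fragments per sample.

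Samples of the same group differed in red cell precursor genes. Alas2, the first enzyme of heme synthesis in red cell precursors, was at 926, 915 and 940 FPKM in the Aged-TBI samples, while Young-TBI held 622, 503 and 379 FPKM. Among the controls, Young-CON 2 (397 FPKM, against 912 and 787) and Aged-CON 1 (911 FPKM, against 458 and 476) stood apart from the other 2 of their group. Haemoglobin transcripts were listed at or near 0 in all samples, with Hbb-bs at most at 0.25 FPKM, so red cell content was followed through the other erythroid genes. The mean log2 value of that list was 6.92 ± 0.52 in Young-CON, 6.82 ± 0.24 in Young-TBI, 6.90 ± 0.49 in Aged-CON and 7.71 ± 0.07 in Aged-TBI (SD, n = 3 each). The first principal component held 32.4% of the variance and the second 18.3%.

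**Figure D1:**
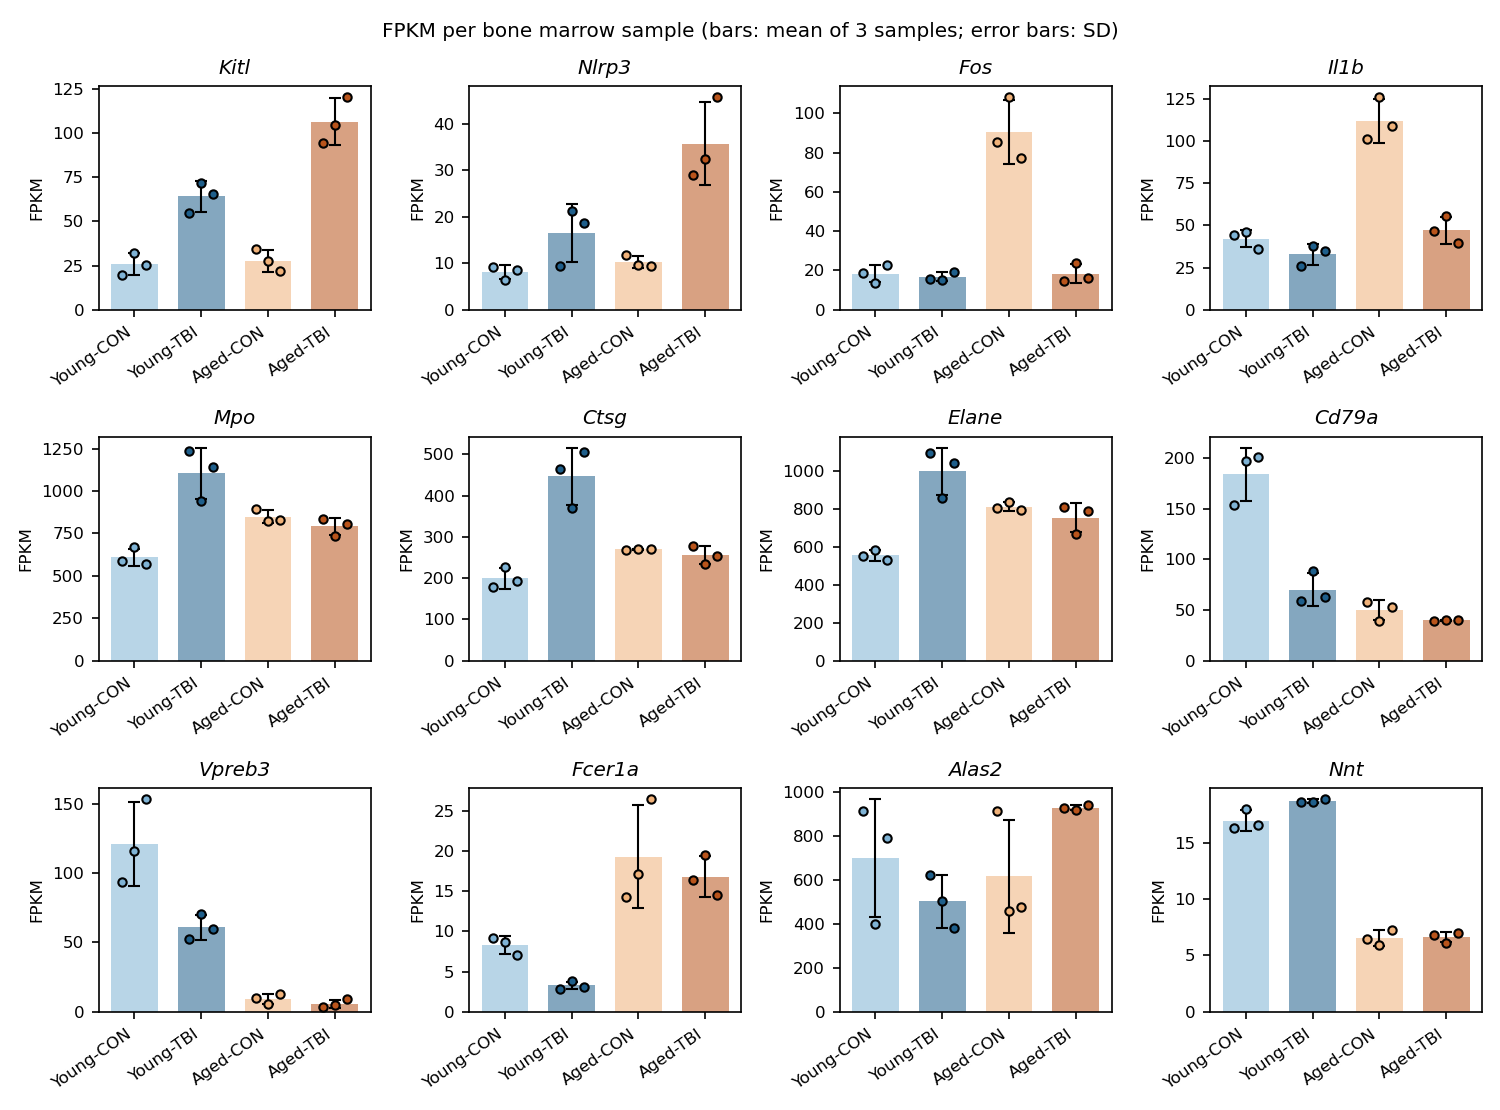
Levels of 12 genes in FPKM in the 4 groups; bars are means of 3 samples, error bars are SD and points are samples. Kitl was higher after injury at both ages, Mpo and Ctsg rose after injury in young mice, Fos and Il1b stood high in Aged-CON, and Cd79a and Vpreb3 were highest in Young-CON.

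The first comparison asks what injury changed in young marrow. By day 3, RNA of the granule enzymes that neutrophil progenitors make had risen, and RNA of B cells, T and natural killer cells and basophils had fallen. Mpo, the gene of myeloperoxidase (GRCm38 chromosome 11, 87793581 to 87804413), rose from 608 ± 52.1 FPKM in Young-CON to 1105 ± 150 FPKM in Young-TBI (SD, n = 3 each), a log2 change of 0.85 (SE 0.10, adjusted p = 0.00293). Cd79a, a signalling chain of the B cell receptor, fell from 184 ± 26.2 to 70.1 ± 16.1 FPKM, a log2 change of −1.39 (SE 0.17, adjusted p = 0.00293). Kitl, which encodes stem cell factor (chromosome 10, 100015630 to 100100416), rose from 25.7 ± 6.21 to 64.2 ± 8.67 FPKM (log2 change 1.31, SE 0.19, adjusted p = 0.00467).

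Of the 11 tested genes of the neutrophil primary granule and progenitor list, 8 rose and the other 3 did not pass, with a median log2 change of 0.84; 10 rose when adjusted over the list alone. The proteases Ctsg, Prtn3, Prss57 and Elane rose by 1.16, 1.13, 0.85 and 0.84, and Ms4a3, a marker of granulocyte and monocyte progenitors, by 0.94 (adjusted p from 0.00174 to 0.00293). Camera called this list (adjusted p = 4.65e-16), with adjusted p = 0.23 with an estimated correlation. Genes of later neutrophil stages moved less. No member of the secondary and tertiary granule list passed in limma (16 tested, median 0.18; 3 higher and 1 lower at an unadjusted p under 0.05), although camera called the list as higher (adjusted p = 0.0431; adjusted p = 0.761 with an estimated correlation). Of 17 mature neutrophil genes only the chemokine gene Ccl6 changed, with a log2 change of −0.81. S100a8 and S100a9 had log2 changes of 0.15 and 0.13 (adjusted p = 0.65 and 0.697), and Csf3r, the receptor of granulocyte colony-stimulating factor, one of −0.22 (adjusted p = 0.535).

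Monocyte genes went both ways. Of 20 tested, 2 rose and 3 fell over all genes, and 6 rose and 5 fell when adjusted over the list alone. Ly6c2, the surface marker of inflammatory monocytes, rose by 0.42 (SE 0.11, adjusted p = 0.0487), as did Cd14 (0.52), while Ace and Nr4a1, which mark patrolling monocytes, had changes of −1.08 and −0.97, and Treml4 one of −0.52. Csf1r and Cebpb did not pass (0.17 and 0.34, adjusted p = 0.416 and 0.107). The other largest rises were of Wfdc17, a secreted protein of activated macrophages (1.79), Stfa2, a cysteine protease inhibitor (1.67), the proteoglycan gene Vcan (1.34), Ms4a6d (1.27) and Ggt1, which breaks down glutathione (1.15), with adjusted p from 0.0044 to 0.0178. The platelet chemokine gene Pf4 had a log2 change of 1.07 that did not pass (SE 0.43, adjusted p = 0.19). No gene of the megakaryocyte and platelet list passed in limma (18 tested, median 0.70; 5 higher at an unadjusted p under 0.05). Camera called that list (adjusted p = 2.67e-06; adjusted p = 0.703 with an estimated correlation).

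Lymphoid genes fell together. In the mature B cell list 14 of 15 fell (median −1.17; 15 when adjusted over the list alone), and in the B cell progenitor list 14 of 20 (median −0.95; 18 over the list alone). The same was seen in the MHC class II list for 9 of 11 (median −1.11; 9 over the list alone). Examples were Fcer2a, the low-affinity IgE receptor (−1.72), Fcmr, the IgM receptor (−1.59), Ms4a1, which encodes CD20 (−1.29), Vpreb2 of the surrogate light chain (−1.71) and Cd79a. The transcription factor gene Pax5 (−1.11) fell too, as did H2-DMb2 and Cd74 of the MHC class II list (−1.52 and −1.23). Of 24 T and natural killer cell genes, 10 fell and 1 rose (median −0.45; 15 and 1 over the list alone). Cd8a and Cd2 each had a log2 change of −1.07, while Nkg7, a cytotoxic granule gene, rose by 0.58. In the basophil and mast cell list 6 of 8 fell (median −0.58; 7 over the list alone), among them Fcer1a of the high-affinity IgE receptor (−1.13) and the basophil protease gene Mcpt8 (−0.81). Camera called all 5 of these lists, each with adjusted p = 0.23 with an estimated correlation. H2-Q5, Apol11a and Apol11b completed the largest falls (−1.57, −1.56 and −1.44). No erythroid gene passed in limma or at an unadjusted p under 0.05 (19 tested, median −0.06). Among 24 genes of beta-adrenergic and cAMP signalling, Crebbp, Nr4a1 and Akap12 fell (4 over the list alone; median −0.02). Of 18 immediate early and heat shock genes, 5 fell (6 and 1 higher over the list alone; median −0.16), among them Jund (−0.63) and Zfp36 (−0.42). Camera called that list as lower (adjusted p = 0.00333; adjusted p = 0.392 with an estimated correlation).

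In total, 606 genes passed in young mice, 235 higher and 371 lower (38.8% higher), and 77 of them by at least 1 on the log2 scale. Quantile normalization gave 296 higher and 320 lower (48.1%), and rescaling without dominant genes 175 and 428 (29.0%). The groups did not overlap for 27.9% of genes, against 10% on average by chance. Many genes move together, so a single chance split can lie well away from 10%, and the excess tests nothing. The count was 272 without Young-CON 2, 168 without Young-CON 3, 190 without Young-TBI 1 and 160 without Young-TBI 3, and 1595 with weights per sample and 1302 with the erythroid covariate. Without Young-CON 1, Young-CON 3, Young-TBI 1, 2 or 3 in turn Ly6c2 lost its call (adjusted p = 0.123, 0.186, 0.166, 0.0514 and 0.182). Apol11a did without Young-CON 1 (0.0961), 2 (0.131) or 3 (0.0803) or Young-TBI 1 (0.168) or 3 (0.102). Ggt1 lost its call without Young-CON 3 (0.0838) or Young-TBI 1 (0.0716) or 3 (0.0679), and Ms4a6d without Young-CON 3 (0.0543) or Young-TBI 3 (0.0609).

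**Figure D2:**
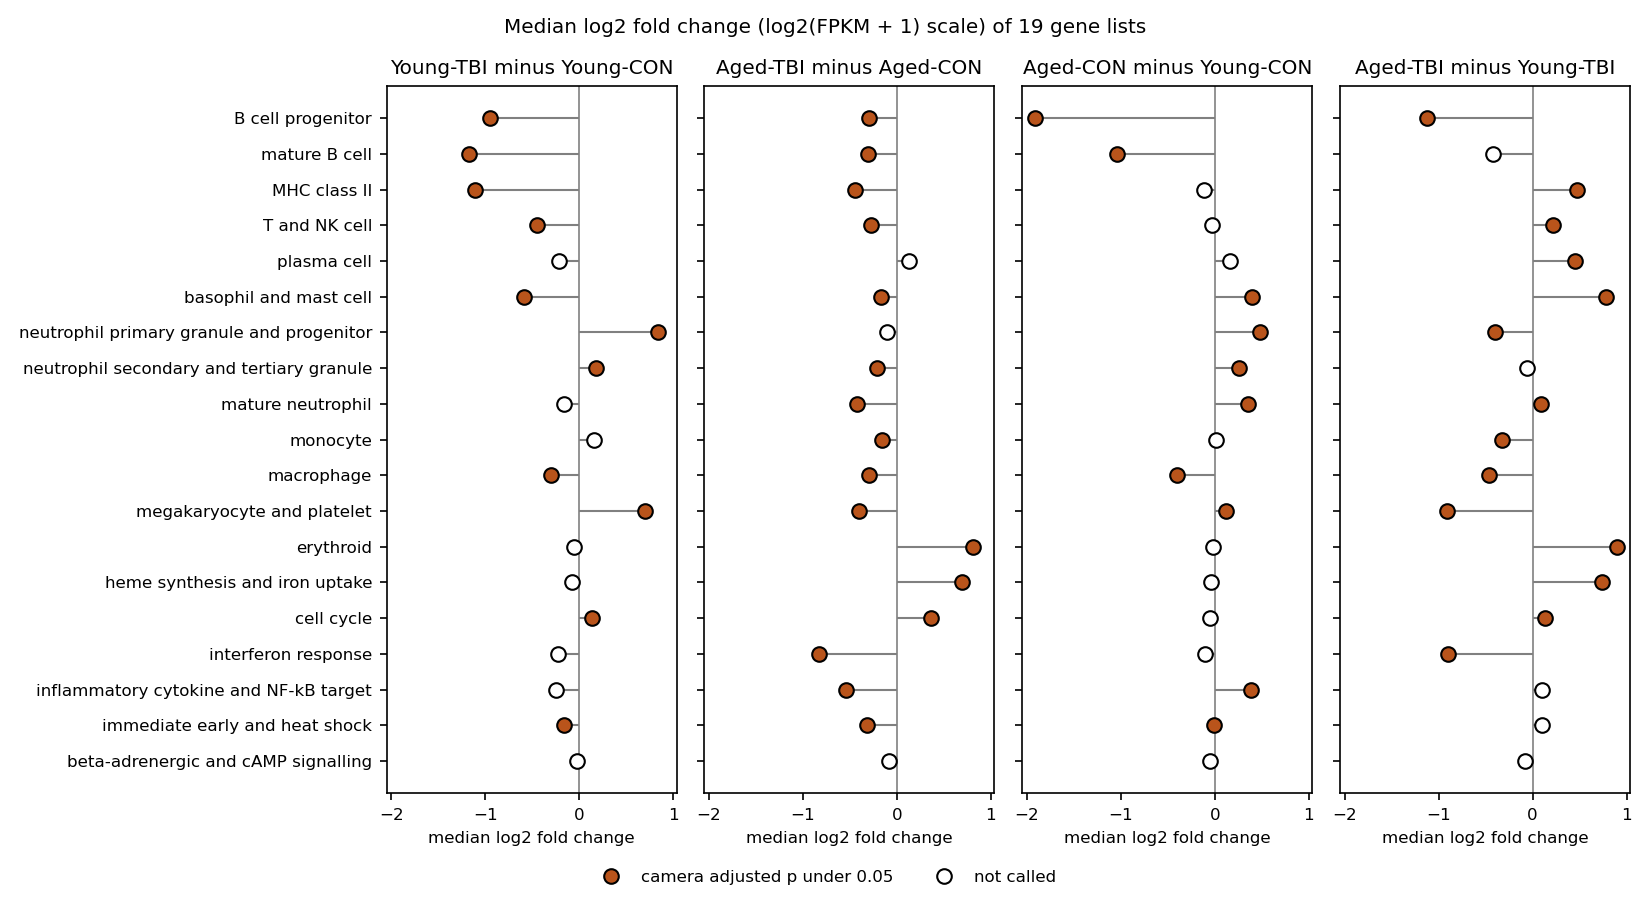
Median log2 change of 19 gene lists in the 4 pairwise comparisons; filled symbols mark lists called by camera at an adjusted p under 0.05 with the preset correlation, none of which was called with an estimated correlation. After injury in young mice the primary granule list stood at 0.84 and the mature B cell list at −1.17, and after injury in aged mice the erythroid list stood at 0.81 and the interferon response list at −0.83.

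The comparison of injured with control aged mice asks whether aged marrow responds in the same way. Kitl rose again, and immediate early and cytokine genes that were high in aged controls fell. Kitl rose from 27.8 ± 6.22 to 107 ± 13.3 FPKM (SD, n = 3 each; log2 change 1.92, SE 0.19, adjusted p = 0.00114). Nlrp3, the sensor of an inflammasome (chromosome 11, 59541568 to 59566956), rose from 10.3 ± 1.32 to 35.8 ± 8.91 FPKM (1.69, SE 0.26, adjusted p = 0.0223). Fos, a transcription factor gene induced within minutes of a stimulus (chromosome 12, 85473890 to 85477273), fell from 90.3 ± 16.2 to 18.3 ± 4.91 FPKM (−2.26, SE 0.20, adjusted p = 0.000744). Il1b, which encodes interleukin-1 beta, fell from 112 ± 13 to 47.1 ± 8.10 FPKM (−1.24, SE 0.16, adjusted p = 0.00645).

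In the immediate early and heat shock list, 4 of 18 genes fell (9 over the list alone; median −0.32): Fos, Junb (−1.13), Zfp36, which destabilises cytokine mRNA (−0.97), and Ier2 (−0.65). In the inflammatory cytokine and NF-kB target list, 4 of 18 fell and Nlrp3 rose (11 and 1 over the list alone; median −0.55). The falls were of Il1b, the neutrophil chemokine gene Cxcl2 (−2.13), Osm, an interleukin-6 family cytokine gene (−1.16), and Ptgs2, which encodes cyclooxygenase-2 (−1.16). Camera called both lists, each with adjusted p = 0.378 with an estimated correlation. Fos was at 18.4 ± 4.48, 16.8 ± 2.24 and 18.3 ± 4.91 FPKM in Young-CON, Young-TBI and Aged-TBI, so the same 3 Aged-CON libraries set this fall and the rise with age among controls.

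In the mature neutrophil list Il1b alone fell of 17 genes (8 lower and 1 higher over the list alone; median −0.42). Camera called it as lower (adjusted p = 4.6e-06; adjusted p = 0.491 with an estimated correlation). The primary granule genes, which rose in young mice, gave no call in aged mice. Mpo was at 849 ± 40.4 FPKM in Aged-CON and 792 ± 49.4 in Aged-TBI (log2 change −0.10, adjusted p = 0.578) and Elane had a change of −0.11 (adjusted p = 0.521). No member of the list passed in limma, nor at an unadjusted p under 0.05 (11 tested, median −0.10). Interferon response genes had a median of −0.83. None of 26 passed over all genes in limma, while 22 were lower at an unadjusted p under 0.05 and 21 over the list alone (camera adjusted p = 3.92e-11; adjusted p = 0.491 with an estimated correlation). The interferon-induced helicase gene Ddx60, outside that list, fell (−1.21, adjusted p = 0.0308), as did Psmb9 of the immunoproteasome (−0.78) and the MHC class I gene H2-Q4 (−1.07). Among B cell progenitor genes none of 20 passed over all genes in limma (6 lower and 1 higher at an unadjusted p under 0.05, 2 and 1 over the list alone, median −0.30). No gene of the MHC class II list passed (7 of 11 lower over the list alone and at an unadjusted p under 0.05, median −0.44).

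Erythroid genes were the higher group in Aged-TBI, by a difference that rests mostly on Aged-CON 2 and 3. The list mean was 7.63, 7.76 and 7.73 in Aged-TBI and 7.47 in Aged-CON 1, but 6.66 and 6.58 in Aged-CON 2 and 3. Of 19 erythroid genes none passed over all genes in limma, yet 17 were higher when adjusted over the list alone and at an unadjusted p under 0.05, with a median of 0.81. Camera called the list (adjusted p = 4.31e-11; adjusted p = 0.491 with an estimated correlation). The heme synthesis and iron uptake list (15 of 17 higher over the list alone, median 0.70) and the cell cycle list (26 of 28, median 0.36) moved with it. Both were also called by camera, and both had adjusted p = 0.491 with an estimated correlation. In Aged-CON 1 these 2 lists stood at 7.36 and 6.43, near the Aged-TBI means of 7.52 and 6.51. The histone gene Hist1h4k rose by 1.22 and Hist1h1c, a linker histone gene, had a change of −0.79; the remaining named genes were Hint3 (0.42) and the nicotinic acid receptor gene Hcar2 (−1.12). Pf4 had a log2 change of −0.74 (adjusted p = 0.315) and Cebpb one of −0.20 (adjusted p = 0.291).

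In aged mice 38 genes passed, 7 higher and 31 lower, and the groups did not overlap for 22.2% of genes; voom on the recovered fragments called 42, with 3 higher and 39 lower. The count was 3264 without Aged-CON 1, 10 without Aged-CON 2, 88 without Aged-CON 3, 11 without Aged-TBI 1, 19 without Aged-TBI 2 and 11 without Aged-TBI 3. It was 3531 without both Young-CON 2 and Aged-CON 1, 3557 with weights per sample. It was 17 with no low-value filter, 21 with no variance trend, 11 in a fit of the 6 aged samples, and 11 with the erythroid covariate, of which 8 were among the 38. Kitl, Fos, Osm, Junb, Il1b, Zfp36, Ptgs2, Ier2 and Hist1h1c passed without any 1 sample. Without Aged-CON 2, Aged-TBI 1, 2 or 3 in turn, calls were lost for Nlrp3 (adjusted p = 0.108, 0.0673, 0.0724 and 0.122), H2-Q4 (0.188, 0.162, 0.12 and 0.122) and Psmb9 (0.102, 0.122, 0.0775 and 0.0651). The same held for Hint3 (0.203, 0.19, 0.0775 and 0.157) and Hist1h4k (0.188, 0.114, 0.12 and 0.155, and 0.0662 without Aged-CON 3). Ddx60 lost its call without Aged-CON 2 (0.0758), Aged-TBI 1 (0.155) or 3 (0.146), Hcar2 without the same samples (0.0582, 0.0939 and 0.0642), and Cxcl2 without Aged-CON 2 (0.0758) or Aged-TBI 3 (0.0642). Without Aged-CON 1, on the other hand, S100a8 (log2 change −0.42, adjusted p = 0.00729), S100a9 (−0.53, 0.00447), Csf3r (0.00341), Ly6c2 (0.0245) and Csf1r (0.049) passed as lower in Aged-TBI. With all samples they had changes of −0.24, −0.34, −0.57, −0.39 and −0.08 that did not pass. The Aged-CON samples left without Aged-CON 1 had erythroid list means of 6.66 and 6.58, against 7.63 to 7.76 in Aged-TBI. Calls of such fits cannot be told apart from a difference in erythroid level. With the erythroid covariate, Nlrp3 (0.301), Il1b (0.138), Cxcl2 (0.121), Ier2 (0.0767) and 6 other named genes lost their calls.

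Set side by side, the injury effects of the 2 ages were weakly correlated across all genes, while the genes called at both ages moved the same way. Noise in 3 against 3 samples lowers such a correlation, so it does not measure how far the responses differ. Over 11767 genes, which are not independent replicates, the log2 changes had a Pearson r of 0.108 and a Spearman rho of 0.103. Kitl was among 2 genes that rose at both ages, where independent lists would share 0.14. The 9 genes that fell at both, where independent lists would share 0.977, were chosen for naming after their values were seen: Ier5, Dusp6, Zfp36, the MHC class I genes H2-K1, H2-D1 and H2-Q4, the interferon-induced gene Gbp9, Hcar2 and Klra2. Of the 606 genes called in young mice, 393 had the same sign in aged mice, and of the 38 called in aged mice 33 had the same sign in young mice. The correlation turned to −0.0522 without Young-CON 2 and to −0.111 without both Young-CON 2 and Aged-CON 1, and it was 0.181, 0.177 and 0.185 without Young-CON 1, Young-CON 3 or Young-TBI 3.

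**Figure D3:**
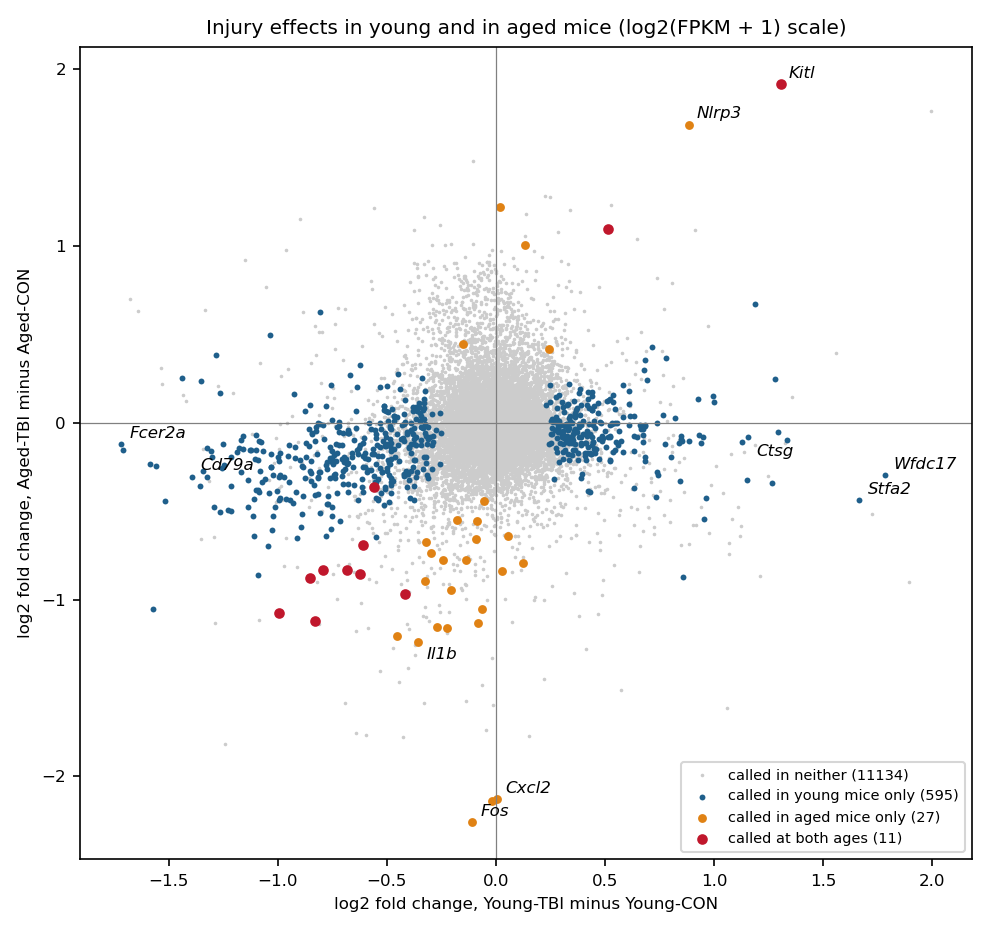
Log2 change after injury in young mice (horizontal axis) against that in aged mice (vertical axis) for each of the 11767 tested genes, each from 3 injured and 3 control samples. Of these genes, 595 passed in young mice alone, 27 in aged mice alone and 11 at both ages, among them Kitl in the upper right.

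Whether the response differed with age was tested as the interaction. The clearest differences were in neutrophil granule genes, which rose in young mice alone, and in Fos, Junb and Osm, which fell in aged mice alone. For Ctsg, the gene of cathepsin G (chromosome 14, 56099881 to 56102574), the levels were 199 ± 24.6, 447 ± 69.3, 270 ± 1.52 and 255 ± 22.1 FPKM in Young-CON, Young-TBI, Aged-CON and Aged-TBI (SD, n = 3 each). The aged injury effect on Ctsg was 1.24 log2 units below the young one (interaction −1.24, SE 0.17, adjusted p = 0.027). Prtn3 (−1.23), Ms4a3 (−1.06), Mpo (−0.96), Elane (−0.95) and Prss57 (−0.92) went the same way, with adjusted p from 0.027 to 0.0478. In all, 6 of 11 primary granule genes passed (9 over the list alone; median −0.92; camera adjusted p = 1.84e-11; adjusted p = 0.552 with an estimated correlation). Among immediate early and cytokine genes, Fos (−2.15), Junb (−1.05) and Osm (−0.94) passed, with adjusted p from 0.027 to 0.0491.

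The further genes below 0 were Stfa2 (−2.10), Cfb, which encodes complement factor B (−1.73), B4galt6 of glycolipid synthesis (−0.99), Hist1h1c (−0.91) and Nkg7 (−0.75). Chchd10, a mitochondrial protein gene, was above 0 at 1.44 (SE 0.24, adjusted p = 0.0491), with −0.81 in young and 0.63 in aged mice. Trib2 (1.09) and Mzb1 (1.53) did not pass (adjusted p = 0.0537 for both). Ccr6, which the rule leaves out for its low level and which was picked after its values were seen, passed (1.13, adjusted p = 0.0491). Ly6c2 had an interaction of −0.81 (SE 0.16, adjusted p = 0.0669), so a difference between the ages in its injury response was not called. B cell genes, which fell in young mice, had positive interactions without a called member in limma. The mature B cell list had a median of 0.82 (13 of 15 over the list alone and at an unadjusted p under 0.05) and the B cell progenitor list one of 0.69 (10 of 20, and 12 at an unadjusted p under 0.05). Both lists were called by camera, and both had adjusted p = 0.552 with an estimated correlation. The erythroid list moved beside these with a median of 0.91, with no member called in limma and 14 of 19 higher at an unadjusted p under 0.05.

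For the interaction 23 genes passed, 2 higher and 21 lower; median-of-ratios scaling gave 5 higher and 15 lower, quantile normalization 6 and 19, and voom on recovered fragments 11 and 33. The count was 0 in limma without any 1 of Young-CON 1, Young-CON 3, Young-TBI 1, Young-TBI 3, Aged-CON 2 or Aged-TBI 3 (1972, 1622, 1939, 1595, 1627 and 1910 genes at an unadjusted p under 0.05). It was 1 without Aged-CON 3, 2 without Aged-TBI 2, 5 without Aged-TBI 1, 100 without Young-TBI 2 and 2105 without Aged-CON 1. Each of the 15 named calls was lost without some sample, and all 15 were also lost with no low-value filter, with the replicate number as a block and with the erythroid covariate. Without Aged-CON 1, S100a8 (−0.57, adjusted p = 0.015), S100a9 (−0.66, 0.0126), Csf3r (0.0269), Csf1r (0.0271) and Cebpb (0.0298) passed, as did Ly6c2 (0.0126), Trib2 (0.00966) and Mzb1 (0.0102). The last 3 also passed without Young-TBI 2, with Ly6c2 at an adjusted p of 0.0429, Trib2 at 0.0404 and Mzb1 at 0.0289. With all samples S100a8, S100a9, Csf3r, Csf1r, Cebpb and Pf4 had interactions of −0.39, −0.48, −0.36, −0.25, −0.54 and −1.81 that did not pass. Aged-CON 1 had the highest erythroid list mean of its group (7.47, against 6.66 and 6.58). Interaction calls without it cannot be told apart from erythroid level.

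Age without injury was compared between the control groups. B cell progenitor genes were far lower in aged marrow, while cytokine, immediate early and neutrophil granule genes were higher. Vpreb3, a chaperone of the pre-B cell receptor, was at 121 ± 30.3 FPKM in Young-CON and 9.29 ± 3.64 FPKM in Aged-CON (SD, n = 3 each; log2 change −3.61, SE 0.32, adjusted p = 5.15e-05). Rag1, which starts antigen receptor gene recombination, was lower by a log2 change of −3.13 (SE 0.23, adjusted p = 1.75e-05). Fos was higher by 2.25 (SE 0.20, adjusted p = 5.63e-05) and Il1b by 1.39 (SE 0.16, adjusted p = 0.000228). The erythroid list differed by a median of −0.02, with no member called in limma or at an unadjusted p under 0.05.

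In the B cell progenitor list 18 of 20 genes were lower with age, over all genes and over the list alone (median −1.91; camera adjusted p = 2.81e-31; adjusted p = 0.169 with an estimated correlation). Among them were the myosin light chain gene Myl4 (−3.62), and Vpreb1 (−2.86) and Igll1 (−2.79) of the surrogate light chain. In the mature B cell list 9 of 15 were lower (12 over the list alone; median −1.04; adjusted p = 0.242 with an estimated correlation), such as the transcription factor gene Spib (−2.41) and Cd72, an inhibitory receptor gene (−2.35). Fam129c, also known from B cells (−3.30), and Akap12, a scaffold of protein kinase A and the only called gene of the beta-adrenergic and cAMP list (−2.86), were among the largest falls. So was the pheromone receptor gene Vmn2r96 (−3.08), whose call voom did not share (adjusted p = 0.181). In the dendritic cell list 3 of 14 genes were lower (8 over the list alone; median −0.45; camera adjusted p = 0.000148; adjusted p = 0.3 with an estimated correlation), including the transcription factor gene Irf8 (−0.47).

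Of 18 genes of the inflammatory cytokine list, 5 were higher in aged controls (7 higher and 2 lower over the list alone; median 0.39; adjusted p = 0.242 with an estimated correlation). They were led by Cxcl2 (2.78), Il1b, Osm (1.21) and Ptgs2 (1.02). In the immediate early and heat shock list 5 of 18 were higher and 1 lower (6 and 3 over the list alone). Its median of −0.01 differed in sign from its mean of 0.22 and from camera, which called it as higher (adjusted p = 0.00199; adjusted p = 0.314 with an estimated correlation). Fos, Junb (1.16) and Zfp36 (0.73) were the examples. The primary granule list had 6 of 11 genes higher (8 over the list alone; median 0.48; adjusted p = 0.242 with an estimated correlation). Ms4a3 was at 0.58, Elane at 0.55, Prss57 at 0.52 and Mpo at 0.48. Olfm4, a secondary granule gene, was higher by 1.41, Gpnmb, a glycoprotein gene of macrophages and osteoclasts, by 2.87, Jchain, which joins IgA and IgM in plasma cells, by 2.01 and Fcer1a by 1.09. S100a8, S100a9 and Csf3r had changes of 0.38, 0.43 and 0.37 that did not pass (adjusted p = 0.216, 0.159 and 0.26), as did Pf4 (0.40), Ly6c2 and Cebpb (0.19 each) and Csf1r (0.03).

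Between the control groups 586 genes differed, 93 higher and 493 lower with age (15.9% higher); median-of-ratios scaling gave 139 and 380 (26.8%) and quantile normalization 129 and 359 (26.4%). The groups did not overlap for 20.4% of genes, against 10% on average by chance, from which a single split of correlated genes can lie well away. The count was 1677 without Aged-CON 1, 340 without Aged-CON 2, 368 without Young-CON 2 and 279 without Young-CON 3. It was 371 among genes with a mean of at least 5 FPKM, 294 in a fit of the 6 controls. It was 2508 with weights per sample, 1020 with the erythroid covariate and 2731 without Young-CON 2 and Aged-CON 1. Mpo lost its call without Young-CON 1 (adjusted p = 0.0554), Young-CON 3 (0.103) or Aged-CON 2 (0.0522), while S100a8 (0.56, adjusted p = 0.00332), S100a9 (0.61, 0.0026) and Csf3r (0.60, 0.00806) passed without Aged-CON 1. Aged-CON 1 had an erythroid list mean of 7.47, against 6.66 and 6.58 in Aged-CON 2 and 3. Fits without it, alone or with Young-CON 2, therefore join age with erythroid level.

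After injury, aged and young marrow differed in B cell, erythroid, interferon, basophil and plasma cell genes. Vpreb3 was at 60.8 ± 9.02 FPKM in Young-TBI and 5.65 ± 3.0 in Aged-TBI (SD, n = 3 each; log2 change −3.30, SE 0.32, adjusted p = 0.000301). Jchain was at 60.3 ± 5.05 and 380 ± 62.5 FPKM (2.63, SE 0.33, adjusted p = 0.00148) and Fcer1a at 3.27 ± 0.485 and 16.8 ± 2.53 FPKM (2.06, SE 0.19, adjusted p = 0.000226). Kitl was higher in aged mice by 0.72 (SE 0.19, adjusted p = 0.034) and Nlrp3 by 1.12 (SE 0.26, adjusted p = 0.0221). Trim10, a gene of red cell maturation, was at 109 ± 22.2 FPKM in Young-TBI and 274 ± 3.90 FPKM in Aged-TBI (1.35, SE 0.31, adjusted p = 0.0238).

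In the B cell progenitor list 17 of 20 genes were lower and 1 higher, Cd24a, both over all genes and over the list alone (median −1.13; adjusted p = 0.499 with an estimated correlation). Myl4 differed by −2.98, Igll1 by −2.82 and Rag1 by −2.79. Among mature B cell genes 5 were higher and 8 lower of 15 (the same over the list alone; median −0.42; not called by camera), and Fam129c was lower (−3.38). In the interferon response list 10 of 26 genes were lower (20 over the list alone; median −0.90; adjusted p = 0.667 with an estimated correlation), among them the chemokine gene Cxcl10 (−1.34) and the antiviral gene Mx1 (−1.10). The primary granule list had 6 of 11 lower (7 over the list alone; median −0.40) and the monocyte list 8 of 20 (10 lower and 1 higher over the list alone; median −0.33). Each was called by camera, and each had adjusted p = 0.667 with an estimated correlation. Ctsg differed by −0.80, Prtn3 by −0.72, Mpo by −0.47, Elane by −0.40, F13a1, a coagulation factor gene of monocytes, by −0.73 and Ly6c2 by −0.62. No megakaryocyte and platelet gene passed in limma (14 of 18 lower over the list alone and at an unadjusted p under 0.05, median −0.91; adjusted p = 0.667 with an estimated correlation), and Pf4 had a change of −1.41 (adjusted p = 0.0605).

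Higher in injured aged mice were 6 of 19 erythroid genes (19 over the list alone; median 0.90) and 5 of 17 heme synthesis genes (16 over the list alone; median 0.74). Both lists were called by camera, with adjusted p = 0.667 with an estimated correlation. Car2, carbonic anhydrase 2, differed by 1.11 and Tmcc2, outside the lists, by 1.56. In the basophil and mast cell list 6 of 8 were higher (7 over the list alone; median 0.78; adjusted p = 0.499 with an estimated correlation), with Mcpt8 at 1.03. In the plasma cell list 4 of 11 were higher and 1 lower (7 and 2 over the list alone; median 0.45; adjusted p = 0.667 with an estimated correlation), with Derl3 of the endoplasmic reticulum at 1.19. Further large rises were of Apol11a (2.41), Apol11b (2.09), Ces1d (1.73), Gpnmb (1.72) and Agpat4 (1.43), and further large falls of Vmn2r96 (−3.25), Nmnat1, an enzyme of NAD synthesis (−2.64), and Dynlt1b (−2.62). S100a8, S100a9, Csf3r, Csf1r and Cebpb had changes of −0.01, −0.05, 0.01, −0.23 and −0.35 that did not pass. Fos and Il1b, high in Aged-CON, were at 16.8 ± 2.24 and 33.0 ± 6.18 FPKM in Young-TBI and at 18.3 ± 4.91 and 47.1 ± 8.10 FPKM in Aged-TBI.

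After injury 1165 genes differed with age, 350 higher and 815 lower (30% higher); median-of-ratios scaling gave 544 and 487 (52.8%) and quantile normalization 462 and 549 (45.7%). The groups did not overlap for 40.0% of genes, against 10% on average by chance, a value that again is no test for correlated genes. The count was 568 without Young-TBI 1, 726 without Young-TBI 2, 314 without Young-TBI 3, 458 without Aged-TBI 1, 451 without Aged-TBI 2 and 416 without Aged-TBI 3. It was 2740 with weights per sample, 2575 without Young-CON 2 and Aged-CON 1, 2279 in a fit of the 6 injured samples. It was 128 with the erythroid covariate, of which 94 were among the 1165. With that covariate 18 of the 30 named calls were lost, among them Ctsg (adjusted p = 0.0667), Cxcl10 (0.0604), Kitl (0.163) and Nlrp3 (0.227). Without Young-TBI 1 or 3 or Aged-TBI 1, 2 or 3 in turn, calls were lost for Kitl (adjusted p = 0.106, 0.103, 0.0607, 0.0879 and 0.118), Elane (0.102, 0.126, 0.0536, 0.109 and 0.0659) and Car2 (0.0659, 0.121, 0.0706, 0.0882 and 0.0712). Without Young-TBI 1, 2 or 3 or Aged-TBI 2 or 3 the same held for Dynlt1b (0.0716, 0.0664, 0.0939, 0.101 and 0.104). Mpo lost its call without Young-TBI 1 (0.0659) or 3 (0.0797) or Aged-TBI 2 (0.072) or 3 (0.0559), and Trim10 without Young-TBI 3 (0.105) or Aged-TBI 1 (0.0669), 2 (0.0707) or 3 (0.0689). Nlrp3 lost its call without Young-TBI 3 (0.0504) or Aged-TBI 2 (0.0567) or 3 (0.0841), and Agpat4 without Young-TBI 2 (0.0516) or 3 (0.0517) or Aged-TBI 3 (0.0609). Ces1d lost its call without Young-TBI 1 (0.051) or Aged-TBI 1 (0.0536) or 3 (0.0534). Pf4 passed as lower without Aged-TBI 2 (−1.98, adjusted p = 0.0134).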

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

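Injury and age combined in 23 genes called for the interaction. The 15 of them named by the rule were Fos (−2.15), Stfa2 (−2.104), Cfb (−1.733), Ctsg (−1.237), Prtn3 (−1.234), Ms4a3 (−1.057), Junb (−1.053), B4galt6 (−0.986), Mpo (−0.956), Elane (−0.951), Osm (−0.937), Prss57 (−0.923), Hist1h1c (−0.914), Nkg7 (−0.747) and Chchd10 (1.437).

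The tests of heat shock genes, of mature neutrophil genes and of all other genes were chosen after this result was seen. Fos, Junb, Ier2, Zfp36, Il1b, Cxcl2, Osm and Ptgs2 were higher in Aged-CON than in Young-CON (median 1.186) and lower again in Aged-TBI. Stress while the tissue was collected may raise such genes, yet 5 heat shock genes had a median of −0.037 (SE over genes 0.038). That SE is over genes of the same samples, which are not replicates, so it does not test the median. The values show only that these heat shock genes as a set did not rise with the pattern. A larger share of mature neutrophils would raise their other genes as well. The list without Il1b had a median of 0.342 (SE over its 16 genes 0.03). The genes of the pattern were picked for being called higher in Aged-CON and lower in Aged-TBI, which inflates their median of 1.186. Comparing these medians therefore cannot show how much of the pattern such a share explains. A smaller erythroid share in Aged-CON would raise all other genes alike. The 11725 tested genes outside the erythroid and heme lists and this pattern had a median of −0.052 (SD 0.288). FPKM is scaled to each sample's total, which holds such a median down, so this value cannot decide. The mean log2 value of the erythroid list was 6.92 ± 0.52 in Young-CON and 6.90 ± 0.49 in Aged-CON (SD, n = 3 each). Fos was at 85.3 FPKM in Aged-CON 1, where that list stood at 7.47. These values argue against a smaller erythroid share. More mature neutrophils, an inflamed state of aged marrow and handling that differed for the 3 Aged-CON samples, without a rise of these heat shock genes, stay open.

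The test of secondary granule genes was chosen after this result was seen; the covariate was chosen after the data were seen, but before the fit with it was run. Primary granule genes rose after injury in young mice (median 0.839) and not in aged mice (interaction −0.923). Loss of B cell RNA might raise the share of all other RNA, but secondary granule genes had a median of 0.179, which argues against it as the whole cause. More erythroid RNA in Aged-TBI would lower the share of granule genes there. With the erythroid covariate the median interaction was −0.765. Its SE of 0.13 is over genes of the same samples, which are not replicates, so it does not test the median. All calls of the list ended. For Prtn3 the change was smaller and its error wider (−1.06, SE 0.17, adjusted p = 0.101 in limma, before −1.23, SE 0.16). Whether erythroid RNA is the whole cause is therefore not settled. The mean log2 value of the primary granule list was 6.87 in Young-CON, 7.57 in Young-TBI, 7.25 in Aged-CON and 7.19 in Aged-TBI. The interaction thus joins a higher list mean in Aged-CON than in Young-CON with a lower one in Aged-TBI than in Young-TBI. A stronger response of neutrophil progenitors in young mice and a response at another time in aged mice stay open.

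The tests of Nnt and of the genes beside it were chosen after this result was seen. Nnt, Wdfy1, Nmnat1 and Lyrm7, of which only Nmnat1 was named by the rule and the others were picked after their values were seen, were lower in aged mice with and without injury. Loss of B cells with age might lower such genes. After injury in young mice, when B cell progenitor genes had a median of −0.946, these 4 had one of 0.104. The 4 genes were picked with their Young-TBI values in view, for a difference between the injured groups too. That choice holds their median up, so it cannot decide. For Nnt the lowest young sample was 2.237 times the highest aged one, and its log2 change with age was −1.254 (SE 0.079, adjusted p = 8.78e-06). C57BL/6J mice carry a deletion in Nnt and other C57BL/6 lines do not, and the labels name no substrain, so an inherited difference between the young and aged mice and age itself cannot be told apart.

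Samples of each comparison were also regrouped, a test set before its own outcome was seen. With 3 against 3 samples there are 10 splits, too few for a share under 0.05. In young injury 1 split, the real one, reached 606 calls and the highest other had 1; in aged injury 1 reached 38 and the highest other had 3; for age after injury 1 reached 1165 and the highest other had 0. Between the controls 2 reached 586, and the split of Young-CON 1, Young-CON 3 and Aged-CON 1 against the rest gave 2150 calls, which points to a structure of the samples that follows their erythroid level. For the interaction 4 of 100 splits, the real one among them, reached 23 calls, and the highest other had 1181.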

How the results depend on the processing

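The named results, 154 in all and 117 of them called, were recomputed under those of 26 alternatives that apply to each, with a sample left out only where its group is compared and a gene only where it passed the filter. No called gene turned its direction. Adding the erythroid list mean as a covariate ended 43 of the 117 calls. Fewer were ended by the minimum log2 change of 1 (32), no low-value filter (27), the replicate number as a block (18), no variance trend (15) and a fit of only the samples compared (13). That covariate takes out what moves with erythroid RNA, whether technical or a response to injury. Of the named calls, 25 of 29 in young injury, 9 of 17 in aged injury, 25 of 26 for age in controls, 21 of 30 for age after injury and 0 of 15 for the interaction were kept whichever sample was left out.

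Counts in young injury were 606 in the fit reported, 1595 with weights per sample, 1302 with the erythroid covariate, 77 at a log2 change of at least 1, 472 with the replicate block, and 160 to 572 without 1 sample. In aged injury 38 became 17 with no low-value filter, 3557 with weights, 21 with no variance trend and 11 with the covariate. It was 3531 without Young-CON 2 and Aged-CON 1, 11 in a fit of only the aged samples, 16 at a log2 change of at least 1, 38 with the block, and 10 to 3264 without 1 sample. Between controls 586 became 371 with a mean of at least 5 FPKM, 2508 with weights, 1020 with the covariate and 2731 without those 2 controls. It was 294 in a fit of only the controls, 150 at a log2 change of at least 1, 518 with the block, and 279 to 1677 without 1 sample. After injury 1165 became 2740 with weights, 128 with the covariate and 2575 without the 2 controls. It was 2279 in a fit of only the injured samples, 143 at a log2 change of at least 1, 1085 with the block, and 314 to 726 without 1 sample.

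For the interaction 23 became 2 with no low-value filter, 39 with a mean of at least 5 FPKM, 5 when rescaled without dominant genes, 2977 with weights and 6 with no variance trend. It was 44 with voom on recovered fragments (21 of the 23 among them), 2 with the covariate, 3045 without the 2 controls, 9 at a log2 change of at least 1, and 0 to 2105 without 1 sample. It was 0 in limma with the replicate number as a block, with 2299 genes at an unadjusted p under 0.05. Numbers of the samples did not pair them: over 18 pairs with the same number in different groups the correlations ran from −0.216 to 0.290, with a median of −0.032. The covariate, voom and the fit without the 2 controls were chosen after seeing the data. The cause of these moves was not tested. Leaving out Aged-CON 1, alone or with Young-CON 2, joins age or injury with erythroid level, so the larger counts of such fits are not clearer effects.

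Correlation of the injury effects, 0.108 in the fit reported and with the replicate block, ran from −0.0522 (without Young-CON 2) to 0.1854 without 1 sample, and was −0.1113 without the 2 controls. Without Aged-CON 1 alone it stayed positive (0.0603), so its sign rests on Young-CON 2. Gene lists called by camera numbered 16, 24, 15, 18 and 18 in the 5 comparisons, in the order of injury in young, injury in aged, age in controls, age after injury and the interaction. With an estimated correlation they were 0 in each, with 7, 2, 6, 2 and 1 lists at an unadjusted p under 0.05, and with fry 9, 2, 8, 4 and 1. In aged injury the covariate gave 15, of which 12 were among the 24. Without 1 sample the counts of lists ran over 13 to 17, 19 to 24, 14 to 18, 16 to 20 and 16 to 22.

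No gene that turned its direction was called. With the erythroid covariate, S100a9 (0.0067), S100a8 (0.104), Cebpb (0.0279) and Csf1r (0.1153) turned in aged injury, S100a8 (0.3675) and S100a9 (0.3425) in age after injury, and Csf3r (0.1261) in the interaction. Without 1 sample, Csf1r ran from −0.2194 to 0.0521 in aged injury and from −0.1084 to 0.163 in age between controls, both turned without Aged-CON 2. In age after injury S100a8 (0.0531) and S100a9 (0.0149) turned with median-of-ratios scaling, and Csf3r with quantile normalization (−0.031). Without 1 sample Csf3r ran there from −0.0822 (without Young-TBI 1) to 0.0761, and S100a8 from −0.075 to 0.024, with a turn without Young-TBI 1 (0.0206), Young-TBI 3 (0.024) or Aged-TBI 3 (0.0021). The list of megakaryocyte and platelet genes, called by camera in aged injury (adjusted p = 0.0377) and between controls (0.0391), turned in both without Aged-CON 3 (adjusted p = 0.909 and 0.729). With the erythroid covariate, lists turned and were called the other way. In aged injury the secondary granule list turned to higher (adjusted p = 0.00607) and the proteasome list to lower (0.000142), and the cell cycle list turned to lower in age after injury (7.34e-09) and in the interaction (1.37e-06).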

Other observations

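Dynlt1b, a dynein light chain gene that the rule named, and its neighbour on chromosome 17, Tmem181b-ps, picked after its values were seen, varied together among the aged samples. Dynlt1b was at 0.08, 3.05 and 3.35 FPKM in Aged-CON and at 5.30, 0 and 0.11 FPKM in Aged-TBI, and Tmem181b-ps at 0.14, 2.40 and 2.07 and at 4.16, 0.09 and 0.07 FPKM (Spearman rho 0.771 over 6 samples). Adjacent genes that are on or off together may reflect a copy number difference between animals, and no DNA was analysed here. Nnt, whose lowest young sample was 2.237 times the highest aged one, is another gene for which an inherited difference stays open.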
